A study of Arabidopsis thaliana with 6 samples.

How the data were processed

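Gene expression was measured on 6 Affymetrix arrays, each hybridised with biotin-labelled cRNA from rosette leaves of Arabidopsis thaliana, 3 from wild-type Columbia-0 plants and 3 from a double mutant. Per the labels, total RNA was extracted with Trizol from plants aged 21 days that had been grown with 12 h of light and kept well watered. Groups and replicate numbers were taken from the sample titles. The sources used here do not say whether the replicates came from separate plants or pools, so the p-values measure the spread between these RNA samples, which may be partly technical.

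The deposited values are log2 expression values per probe set; per the submitters' processing notes they were made with RMA and limma under R 2.9.0. RMA corrects background, quantile-normalizes the arrays and summarises the probes of a probe set. It compresses large folds of weakly expressed genes, because their values lie close to the background. No detection calls were used, so a named gene is described as near the background in a group where each array of that group reads below its own lower quartile, and its change is then given as a lower bound. The array medians of the deposited log2 values ran from 5.81 to 5.91. The authors' deposited table also gives a limma comparison of the double mutant with the wild type, as log2 differences with p-values, adjusted p-values, a moderated statistic and a log odds score; the model terms and the adjustment method are not given in the sources used here. Its log2 differences matched the differences between group means of the deposited values to within 6.7e-09, which sets the direction as double mutant minus wild type. Nothing from the authors' deposited table entered the tests. No scan dates, slides, detection calls or scanner intensities were used here, so batches could not be examined, and the number of arrays limits the precision.

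The values were used as deposited. The 64 control probe sets were left out of the tests, which leaves 22746 of 22810 probe sets. Genes were named through the array's annotation table, which is dated and incomplete: 13513 probe sets name 1 gene, 503 name several and 8730 are unnamed here. Of the first kind 13436 matched a row of the RefSeq gene table of assembly TAIR10.1, and 77, which include mitochondrial genes, did not. The matched probe sets stand for 13286 genes. For gene-level tests the probe set with the highest mean over the 6 arrays was kept. Among 144 genes with over 1 probe set, 4 had probe sets called in opposite directions and 76 had probe sets of which some were called and others were not. No genome build is given in the sources used here, so no coordinates are printed. The TAIR10.1 table was used for names and gene order and to choose the genes near centromeres and near the targeted loci.

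Each probe set was tested with limma 3.58.1 under R 4.3.3 (lmFit and eBayes, two-sided, genotype as the only term), with Benjamini-Hochberg adjustment over 22746 probe sets and a threshold of 0.05. The total degrees of freedom were 10.6. For single genes an exact two-sided permutation test of the 6 values was also run; with 3 arrays against 3 its smallest possible p is 0.1, so it cannot reach 0.05. There were 29 gene lists with 457 genes fixed before the data were examined, of which 55 genes are named on the array; 5 lists have no named gene. Lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 3 lists tested; the alternative estimates the correlation for each list. Genes within 2.5 Mb of a centromere were tested in the same way. Calls within 2 Mb of the targeted loci were compared with calls elsewhere by Fisher's exact test, two-sided. Tests of transposable element genes and of cytosolic ribosomal protein genes were also planned; they were not run, since 0 of the measured genes carry such an annotation in the tables used here.

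The genes named in the text follow a rule fixed before the data were examined. They are the MLK family, the 10 largest increases and 10 largest decreases among called probe sets that name 1 gene and whose groups of arrays do not overlap, and from each list up to 3 called members with the smallest adjusted p, or, where none was called, the member with the largest absolute statistic. Genes named outside this rule are marked as such. The analysis by gene order, the organelle genes, the annotated pseudogenes and the families defined by shared gene symbols were added after the data were examined. The search by gene order looked for the strongest contiguous run of genes on each chromosome among 5810 genes with a mean log2 value of at least 5.88, against 100 shuffles of gene order. Numerical work and plots used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

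The tests were checked on simulated data with the real means and spreads of 22746 probe sets and 200 changed probe sets in each of 5 simulations. For double mutant against wild type, limma recovered 40.4% of changes of 0.5 on the log2 scale, 94% of changes of 1, 98.8% of changes of 2 and 100% of changes of 4, and 3.7% of its calls were false. In the real data 8757 probe sets were called, so the adjusted threshold is less strict there than in these simulations. The simulated shares need not hold for the real comparison. Camera found 100 of 100 simulated lists of 6 genes lowered by 1.5, and called 5 of 100 unchanged lists. The genes of these lists were simulated independently, all shifted the same way, and counted at an unadjusted p under 0.05. In the real data far more probe sets change and lists can move both ways, so these counts need not hold there. The search by gene order found 20 of 20 planted runs of 100 genes shifted by 0.8. Alternatives were a replicate block, repeated quantile normalization, centring of the arrays, a low-signal filter keeping 70% of probe sets, a mean-variance trend, array weights, probe sets that name 1 gene, each array left out in turn, other windows, an estimated correlation, a minimum log2 change of 1 and the authors' deposited table.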

Results

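Transcript levels were compared between rosettes of wild-type Arabidopsis and of a double mutant with reduced expression of AT3G03940 and AT5G18190. These genes encode MLK2 and MLK1, protein kinases of a small family that also holds MLK3 and MLK4. The series title places the work in a study of osmotic stress and of a phosphate mark on threonine 3 of histone H3 near centromeres; the arrays analysed here are from well-watered plants only. There were 3 arrays per genotype. Pearson correlations between arrays, taken across probe sets, ran from 0.9932 to 0.9957 within the wild type and from 0.9967 to 0.9976 within the double mutant, against 0.9673 to 0.9696 between genotypes. The SD of the log2 difference between 2 arrays was 0.161 to 0.266 within a genotype and 0.567 to 0.588 between genotypes. No 2 arrays were identical.

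MLK1 (AT5G18190) was the targeted gene that could be followed on the array. Its log2 value was 7.92, 7.74 and 7.63 in the wild-type arrays and 3.42, 3.57 and 3.36 in the double mutant arrays. The mean thus fell from 7.77 ± 0.15 to 3.45 ± 0.11 (SD, n = 3), a difference of -4.32 (SE 0.10), with limma adjusted p = 2.1e-09. In the double mutant it lay below the lower quartile of each array, near the background, so the fall is a lower bound, at least 19.9-fold. An exact permutation test of the 6 values gave p = 0.1, the smallest this design allows. One label writes this locus with a digit missing, and it was read as AT5G18190. MLK2 (AT3G03940) was not analysed here, as no probe set names it. Where the mutations lie relative to the probes is not given in the sources used here. Of the other family members, MLK4 was at 8.65 ± 0.11 in the wild type and 8.82 ± 0.09 in the double mutant (SD, n = 3; limma adjusted p = 0.19). The probe sets of MLK3 differed: one rose by 0.59 (SE 0.15, limma adjusted p = 0.0099) and the brighter one differed by -0.17 (SE 0.09, adjusted p = 0.15).

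The double mutant differed from the wild type in a large part of the measured transcriptome. Of 22746 probe sets, 8757 (38.5%) changed at an adjusted p of 0.05, of which 4502 were higher and 4255 were lower in the double mutant. A change of at least 1 on the log2 scale as well was seen for 1614 probe sets, 989 higher and 625 lower. Among probe sets that name 1 gene, 2430 were higher and 2297 lower. The 3 arrays of one genotype lay wholly above or below those of the other for 11300 probe sets (49.7%), where chance gives 10%. The same arrays also differ in values that RNA preparation or labelling can change. The 25S ribosomal RNA control differed by 6.26. For 3 of 6 control pairs, from actin and GAPDH, the 5′ end rose against the 3′ end in every double mutant array. Whether preparation or the genotype gave these differences cannot be told here. The counts of changed probe sets therefore do not separate genotype from preparation. The authors' deposited table holds 8756 probe sets at the same threshold, 4502 higher and 4254 lower.

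Among probe sets that name 1 gene, the 10 largest increases were between 3.45 and 4.40 on the log2 scale. AT3G28220, which encodes a protein with a TRAF-like domain, rose from 4.82 ± 0.13 to 9.22 ± 0.08 (SD, n = 3), a difference of 4.40 (SE 0.10) or 21.1-fold. ATPMEPCRB, a pectin methylesterase of the cell wall, rose by 4.21 (SE 0.13), and AT4G22470, a member of the lipid transfer protein family, rose by 3.99 (SE 0.14). GAT1_2.1, a glutamine amidotransferase, rose by 3.65 (SE 0.11), and the peroxidase gene AT5G39580, near the background in the wild type, rose at least 11.3-fold to 7.10 ± 0.20 (SD, n = 3). The bHLH transcription factor gene AT5G50915 rose by 3.46 (SE 0.13); it lies in an interval of chromosome 5, described with the genes by chromosome position, in which most expressed genes were higher. The other 4 of the 10 largest increases were plastid-encoded. ndhK and ndhH, subunits of the plastid NADH dehydrogenase-like complex, rose by 4.31 (SE 0.21) and 3.77 (SE 0.15). psbB, which encodes a core protein of photosystem II, rose by 3.91 (SE 0.15), and ycf3, needed for the assembly of photosystem I, rose by 3.45 (SE 0.25). The limma adjusted p of these 10 genes was at most 1.5e-06. A control probe set for 25S ribosomal RNA moved with genotype in the same direction, from 5.93 ± 0.76 to 12.20 ± 0.12 (SD, n = 3).

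Among the same probe sets the largest decrease was that of AT2G20870, annotated as a cell wall protein, which fell from 10.15 ± 0.10 to 4.93 ± 0.19 (SD, n = 3), a difference of -5.21 (SE 0.11) or 37.1-fold. AT5G22430 and AT5G15780, both of the pollen Ole e 1 allergen and extensin family, fell by 4.17 (SE 0.12) and 3.40 (SE 0.19). EXLB1, an expansin-like gene, fell by 3.56 (SE 0.16), and the GDSL-type lipase gene AT5G33370 fell by 3.43 (SE 0.12). COR15B, which encodes a cold-induced chloroplast protein, fell by 3.66 (SE 0.11), and AT4G30650, of the low temperature and salt responsive protein family, fell by 3.31 (SE 0.20). QQS, an orphan gene linked to starch content, fell to near the background, by at least 3.32 (SE 0.11), and AT4G16146 fell from 8.35 ± 0.18 to 5.05 ± 0.12 (SD, n = 3), or 9.84-fold. With MLK1 these make up the 10 largest decreases among them, and their limma adjusted p was at most 3.9e-07.

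**Figure D1:**
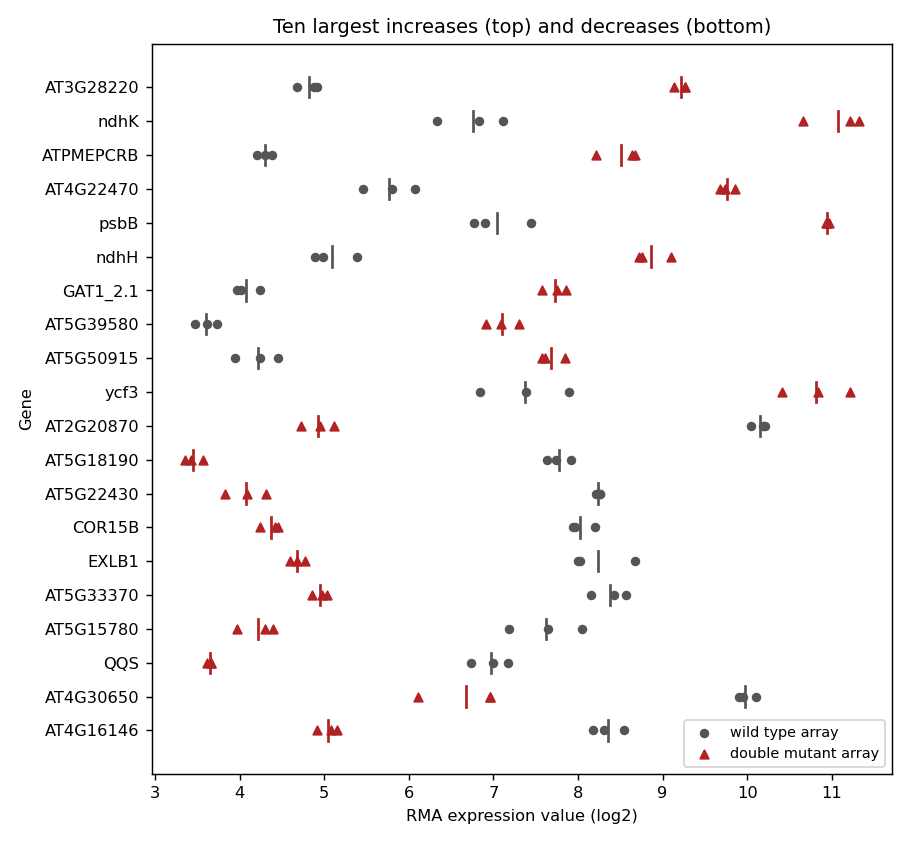
Log2 RMA expression values of the 10 largest increases and the 10 largest decreases among called probe sets that name 1 gene, 1 row per gene. Circles are the 3 wild-type arrays, triangles the 3 double mutant arrays, and short vertical lines the group means; in each row the genotypes do not overlap, from AT3G28220 (difference 4.40) and AT2G20870 (-5.21) to ycf3 (3.45) and AT4G30650 (-3.31).

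Most of the measured genes of the cold and CBF list fell. Of its 14 genes 6 were measured, with none of its CBF genes among them. Of the 6 measured genes, 4 fell, 1 rose and 1 did not pass. COR15B fell from 8.03 ± 0.15 to 4.37 ± 0.12 and COR27 from 7.30 ± 0.11 to 4.49 ± 0.13 (SD, n = 3), and COR28 fell to near the background, by at least 3.21 (SE 0.09), from 6.71 ± 0.07 (SD, n = 3). COR27 and COR28 encode small proteins that are induced by cold and also act in the circadian clock. ZAT10, a zinc finger repressor induced by many stresses, moved the other way and rose by 1.56 (SE 0.12, limma adjusted p = 3e-06). COR15A, a list member outside the naming rule, fell by 1.05, and COR47, likewise outside it, differed by 0.05 (adjusted p = 0.73). COR15A and COR15B are related genes, as are COR27 and COR28, so the 4 falls may not be independent. Adjusted over the list alone, 5 of the 6 genes changed. Camera called the list lower (adjusted p = 0.0036); the adjusted p was 0.088 with an estimated correlation, which does not pass.

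Some nuclear genes of the light harvesting and photosystems list were higher in the double mutant, by under 1 on the log2 scale. Of 7 measured genes of that list, 3 rose and 4 did not pass. RCA, the Rubisco activase, is on the list but is not an antenna or photosystem gene. It rose by 0.60 (SE 0.08) from 12.94 ± 0.05 to 13.54 ± 0.03 (SD, n = 3). The antenna gene LHCB4.3 rose by 0.55 (SE 0.11), and PSBY, a small subunit of photosystem II, rose by 0.49 (SE 0.10). Adjusted over the list alone, 3 of the 7 genes changed. Camera called the list higher (adjusted p = 0.027), and the adjusted p was 0.11 with an estimated correlation and 0.076 with the low-signal filter.

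Of 5 measured genes of the cell cycle and replication list, AUR2, which encodes an Aurora kinase, rose by 0.70 (SE 0.10) and 4 did not pass; 1 changed adjusted over the list alone, and camera gave an adjusted p of 0.35, and an adjusted p of 0.39 with an estimated correlation. HASPIN, the gene of a kinase that phosphorylates histone H3 at threonine 3, was singled out after its values were seen. It was at 4.57 ± 0.40 in the wild type and 4.74 ± 0.17 in the double mutant (SD, n = 3; limma adjusted p = 0.48).

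The other 21 lists with a named gene had fewer than 5 measured genes and no test as a list. Over all 29 lists, 55 distinct genes were measured, of which 19 rose, 14 fell and 22 did not pass. GI, which links the circadian clock to flowering and is the only gene of the evening clock list that is named on the array, fell by 1.56 (SE 0.10), and AGL24, a flowering-time gene, fell by 0.64 (SE 0.15). HYH, a light-signalling bZIP factor near the background in the wild type, rose by at least 0.74 (SE 0.12). UPOX, a mitochondrial marker of oxidative stress, rose by 1.61 (SE 0.09), while the second measured gene of that list did not pass. LTI30, a dehydrin and the only measured gene of the ABA and dehydration list, rose by 0.66 (SE 0.11). Both auxin-conjugating enzymes measured from the auxin list changed, in opposite directions: GH3.5 fell by 0.81 (SE 0.09) and GH3.3 rose by 0.77 (SE 0.17). IAA29, an auxin-response repressor, fell by 1.08 (SE 0.11). EXPA8, an expansin, fell by 0.93 (SE 0.12), XTH33, a xyloglucan-modifying enzyme, rose by 0.57 (SE 0.14), and the remaining measured gene of the fixed cell wall expansion list did not pass. BCAT4, which starts the chain elongation of methionine for glucosinolates, rose by 1.48 (SE 0.13), and UGT74B1, which acts later in glucosinolate synthesis, fell by 0.49 (SE 0.10). SAG29, a senescence-associated sugar transporter, rose by 1.48 (SE 0.11), and PYK10, a root beta-glucosidase and the only measured gene of the root list, rose by 0.52 (SE 0.10). ARR15, a cytokinin-response regulator near the background in the wild type, rose by at least 0.72 (SE 0.11).

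PDF1.2, a plant defensin of the jasmonate and ethylene response, rose by 1.99 (SE 0.11), and DFR of anthocyanin synthesis rose by 0.76 (SE 0.13); both lie in the interval of chromosome 5 in which most expressed genes were higher, as does COR27, which fell. Among defence genes, GRX480, a glutaredoxin of the salicylic acid response, fell by 0.64 (SE 0.15). Calls of 4 genes were lost in some fits that left out 1 array, while none of them changed direction. Over all such fits the change was 0.3 to 0.42 for SAG101 and -0.5 to -0.3 for THI2.1. It was 0.3 to 0.4 for WRKY6 and 0.25 to 0.55 for ARR16. SAG101, a lipase-like defence gene, rose by 0.36, with adjusted p = 0.059 without wild-type replicate 3 and 0.072 without double mutant replicate 1. THI2.1, a thionin, fell by 0.39, with adjusted p = 0.08, 0.068, 0.1 and 0.11 without wild-type replicates 2 and 3 and double mutant replicates 1 and 2. WRKY6 rose by 0.35, with adjusted p = 0.053 without double mutant replicate 3. ARR16 rose by 0.39 (adjusted p = 0.048), and passed only without double mutant replicate 3 among the fits that leave out 1 array; its adjusted p was 0.063, 0.12 and 0.078 without wild-type replicates 1, 2 and 3, and 0.19 and 0.13 without double mutant replicates 1 and 2.

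Lists related to chromatin and heat stress held few measured genes and no call. CENH3, the centromeric histone H3, was at 4.34 ± 0.21 in the wild type and 4.41 ± 0.15 in the double mutant (SD, n = 3; limma adjusted p = 0.71). DME, a DNA glycosylase that removes methylated cytosine, was at 6.62 ± 0.15 and 6.76 ± 0.03 (SD, n = 3; limma adjusted p = 0.29). Of the heat shock genes, HSP22 was at 3.44 ± 0.19 and 3.48 ± 0.21 (SD, n = 3, limma adjusted p = 0.84), near the background in both genotypes. The guard cell regulator FAMA was at 7.43 ± 0.15 and 7.26 ± 0.16 (SD, n = 3; limma adjusted p = 0.27). From the reference gene list UBC21 fell by 0.46 (SE 0.09, limma adjusted p = 0.0026), and the other one did not pass. The morning clock, sugar starvation, flower organ, seed storage and shoot meristem lists were not analysed here, as they have no named gene on the array.

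Pericentromeric genes were examined because the series title concerns these regions. Of 1521 genes within 2.5 Mb of a centromere, 99 rose and 183 fell in the double mutant, 18.5% in all, against 37% of the 11765 other genes. The pericentromeric genes were also more weakly expressed, with a median log2 level of 3.46 against 5.69. Their median change was -0.03 against -0.01 elsewhere and their mean change -0.05 against 0.02. A shift of these genes against the others did not pass with camera (p = 0.14; p = 0.54 with an estimated correlation).

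Genes beside the targeted loci were called about as often as others. Of 963 genes within 2 Mb of AT3G03940 or AT5G18190, the targeted genes left out, 334 (34.7%) changed, against 4304 of 12322 (34.9%) elsewhere (odds ratio 0.989, Fisher's exact test, p = 0.89). With the low-signal filter the odds ratio was 0.769 (Fisher's exact test, p = 0.00078).

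A long interval of chromosome 5 was higher in the double mutant; it was found after the data were seen, and its borders were chosen from the same values. Between AT5G40450 and AT5G55000, 753 genes were measured, of which 451 rose, 29 fell and 273 did not pass. Among the 392 of them above the median level, the median change was 0.84 (95% bootstrap interval 0.79 to 0.90), or 1.8-fold, with quartiles of 0.55 and 1.11, and 94.9% lay above 0 against 45.9% elsewhere. The median was 0.85, 0.85 and 0.82 in the 3 double mutant arrays, each against the wild-type mean. The wild-type arrays, each against the other 2, had medians of -0.01, 0.02 and 0.02. The nearest 25 genes before the interval had a median of -0.21 and the nearest 25 after it a median of 0.04. Running medians of 25 genes were 0.67 to 1.04 for windows wholly inside the interval and -0.41 to 0.32 for windows wholly outside it on all 5 chromosomes. The run statistic was 14.28, and 0 of 100 shuffles of gene order gave a run as strong. The 361 weakly expressed genes of the interval had a median change of 0.09.

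**Figure D2:**
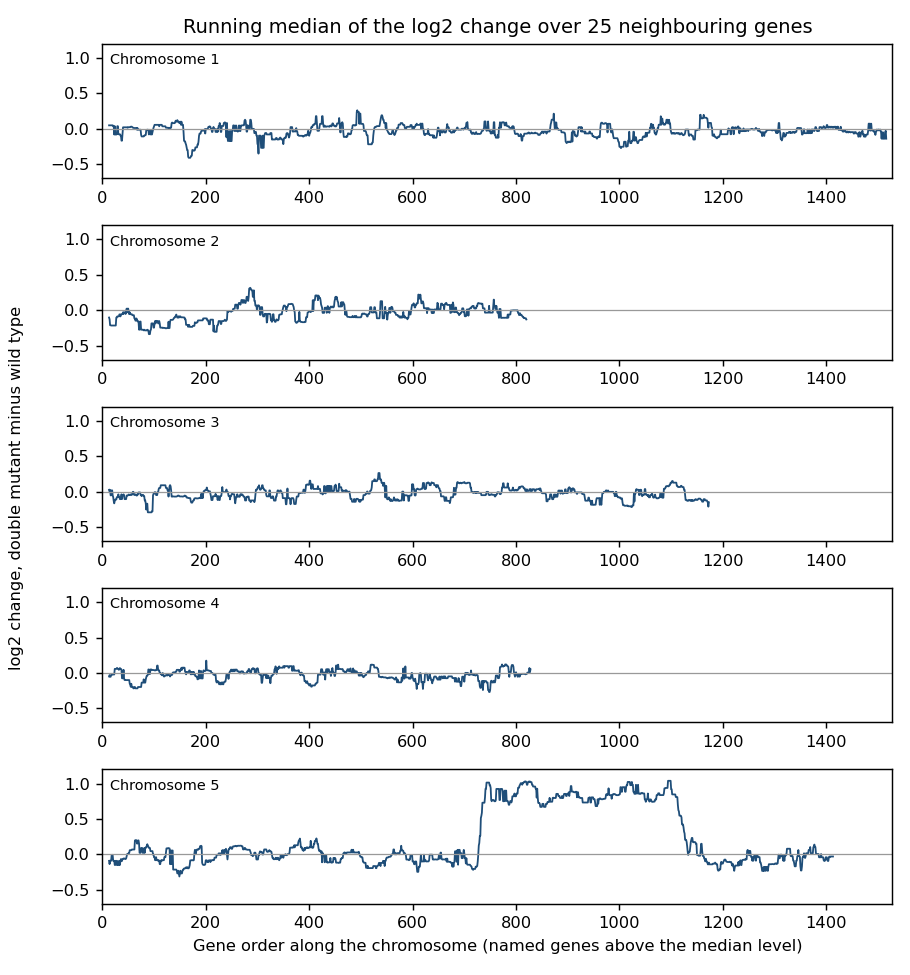
Running median of the log2 change, double mutant minus wild type, over 25 neighbouring genes in gene order, with a panel for each of the 5 chromosomes and 0 as a grey line. For windows wholly outside the interval of chromosome 5 that runs from AT5G40450 to AT5G55000 the curve lies between -0.41 and 0.32, and for windows wholly inside it between 0.67 and 1.04.

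Plastid-encoded transcripts were mostly higher in the double mutant; this set too was formed after the data were seen. Of 69 measured plastid genes 38 rose, 11 fell and 20 did not pass, with a median change of 0.49. Camera gave p = 3.5e-09, but p = 0.22 with an estimated correlation. The control probe set for 25S ribosomal RNA differed between the same arrays by 6.26 in the same direction. Genes of some transcription units differed widely, while those of others moved together: atpB and atpE differed by 0.18 and 0.21, and psbK and psbI by 0.35 and 0.31. In the wild type atpB and atpE already read 13.19 and 13.18. The array maxima were 13.63 to 13.81, which may limit how far these 2 genes could rise. In the unit that starts with psbB, psbB differed by 3.91 and psbT by 2.80, and psbH, petB and petD by 0.29, -0.02 and -0.37. In the ATP synthase unit rps2, the first gene, differed by 0.48, and atpI, atpH, atpF and atpA differed by 2.94, 2.56, 2.01 and 1.17. In the unit of ndhH the first gene differed by 3.77 and the last, ndhD, by -0.34. In the unit of ndhC the first gene differed by -0.24 and the next, ndhK, by 4.31. In the petL unit the first gene was lower, with -2.50 for petL and -1.60 for psaJ. These plastid genes were named after their values were seen.

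**Figure D3:**
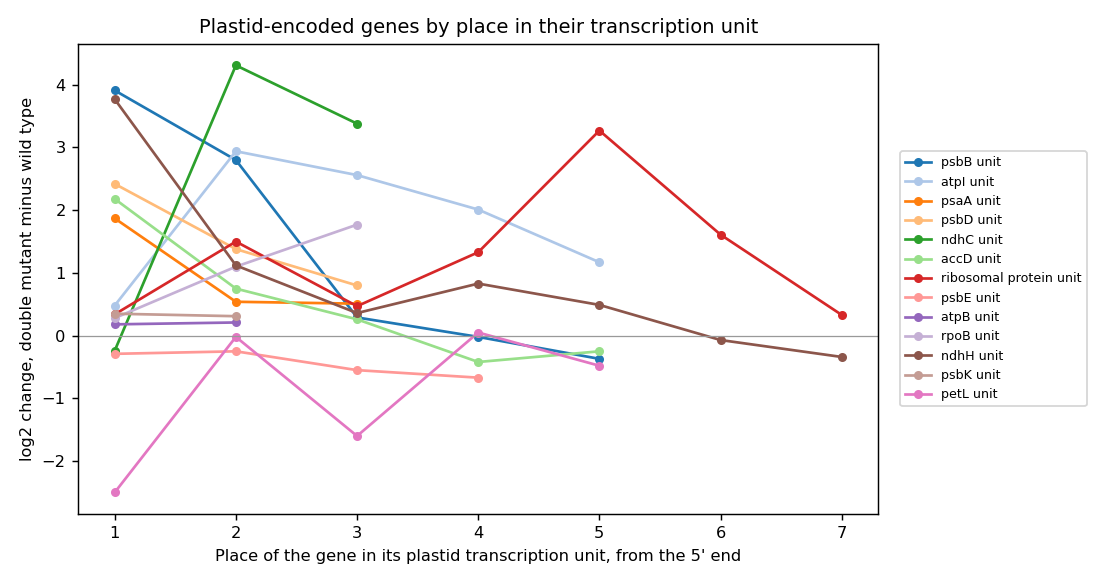
Log2 change, double mutant minus wild type, of 54 plastid-encoded genes against the place of the gene in its transcription unit, counted from the 5′ end. Each point is a gene and each line joins the measured genes of 1 of 13 units; psbB (3.91) and ndhH (3.77) stand at the start of units that end near 0, and petL (-2.50) is the lowest point.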

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

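The tests in this part were chosen after the results were seen, except the camera tests of the gene lists in the real grouping. Those were planned, with the preset and with the estimated correlation. A control probe set for 25S ribosomal RNA, which takes no part in the gene tests, stood far apart between the genotypes. It read 5.45, 6.81 and 5.53 in the wild-type arrays and 12.19, 12.08 and 12.32 in the double mutant arrays, a difference of 6.26 on the log2 scale or 76.9-fold (exact permutation p = 0.1, the smallest possible). It is the only one of the 64 control probe sets that differed by 1 or more, and the next largest difference was 0.83, for 5S ribosomal RNA, which was lower in the double mutant.

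Plastid-encoded transcripts rose beside 25S ribosomal RNA, and both kinds of RNA mostly lack the long poly(A) tails that the usual labelling starts from, so a difference in RNA preparation or labelling may underlie both. If RNA from organelles was labelled more in general, mitochondrial transcripts should rise too: the 6 mitochondrial probe sets above the median level had a median change of 0.22 (95% bootstrap interval -1.18 to 1.39), against 0.56 (0.34 to 1.13) for 64 plastid genes, which leaves this open. If cDNA was shorter in the wild-type arrays and began at 3′ ends, the rise should be greatest at the 5′ ends of plastid transcription units. The mean rank correlation of the change with place was -0.27 over 13 units (permutation test, two-sided, p = 0.15), in that direction but within chance. As these RNAs mostly lack long poly(A) tails, cDNA need not begin at the 3′ end of a unit, so place cannot decide this. The unit borders were set from general knowledge. Nuclear control transcripts gave a mixed answer. The 6 control pairs come from actin, GAPDH and ubiquitin, each with a second pair. For 3 of them the 5′ end rose against the 3′ end in every double mutant array. These rose by 0.67 and 0.35 for actin and by 0.38 for GAPDH. The second GAPDH pair moved by 0.03, and the ubiquitin pairs by -0.19 and 0.06. These explanations, and a change of ribosomal and plastid RNA in the double mutant itself, cannot be told apart here, because no labels used here give batches of preparation and the control pairs moved in different ways, some of them by more than the spread between arrays.

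The number of changed probe sets was also set against other groupings of the arrays. The real grouping gave 8757 probe sets, and it was the 1 of 10 splits of the 6 arrays to give as many. In limma the other 9 splits gave 0 at most, and 137 to 413 probe sets at an unadjusted p under 0.05, against 10485 for the real grouping. Each of the other splits mixes the genotypes, so the genotype difference widens the spread within its groups. Low counts from them were therefore built in and do not show what arrays without a difference would give. For the gene lists the real grouping gave 2 of 3 lists tested and the highest of the other splits was 0. With an estimated correlation neither of these lists passes (adjusted p = 0.088 for the cold and CBF list and adjusted p = 0.11 for the light harvesting list). With 10 splits the share cannot fall under 0.05.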

How the results depend on the processing

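The settings without the chromosome 5 run and without plastid-encoded genes were chosen after the data were seen. They left out only probe sets that name 1 gene there, so any that are unnamed or name several genes stayed in. The other settings were fixed before the data were examined. The call of AT5G18190 held in every setting tried, with differences of -4.38 to -4.24 when each array was left out in turn; pericentromeric genes were not called in any. Leaving out each array gave 6985 to 8834 changed probe sets, 3651 to 4536 higher and 3334 to 4298 lower. No count moved by over 1.5 times under repeated quantile normalization (8894), centring (8891), the low-signal filter (8068), a mean-variance trend (8915), array weights (9390), without the chromosome 5 run (8219) or without plastid-encoded genes (8719). Centring put 44.4% of calls on the higher side against 51.4% as deposited. With probe sets that name 1 gene there were 4585 changed, 2367 higher and 2218 lower, since fewer were tested; with a minimum log2 change of 1 there were 1614, 989 and 625, by construction. Gene lists changed fell from 2 to 1 with the low-signal filter and to 0 with an estimated correlation. In the latter setting 1 list had an unadjusted camera p under 0.05. The estimated correlations were -0.13 for the cold and CBF list and 0 for the light harvesting list, not above the preset 0.01. They argue against stronger correlation between genes as the cause of that loss. Camera also uses fewer degrees of freedom when it estimates the correlation than with a preset one. How much of the loss comes from this was not tested. Genes near the targeted loci had an odds ratio of 0.989, which crossed 1 with no call to 1.05 (quantile normalization), 1.01 (array weights), 1.05 (4 Mb window), 1.06 (1 Mb window) and 1.07 (without the chromosome 5 run), and was 0.769 with the low-signal filter (Fisher's exact test, p = 0.00078); the cause was not tested. Leaving out each array gave 0.885 to 1.01. Of 56 named probe sets 6 had a call or direction that changed. They include the 4 calls given above that were lost in some fits with 1 array left out. The uncalled HSP22 read -0.01 with centring and -0.08 to 0.13 when each array was left out. It was below 0 without wild-type or double mutant replicate 2. The uncalled CENH3 read -0.02 with array weights and -0.04 to 0.17 when each array was left out. It was below 0 without wild-type replicate 2 or double mutant replicate 3. ARR16 also lost its call with quantile normalization, centring, the trend and 1-gene probe sets (adjusted p 0.051 to 0.07). No sign of pairing by replicate number was seen: deviations of same-numbered arrays correlated at -0.05, -0.12 and -0.17, and no array correlated best with its own number. With so few arrays this cannot exclude that same-numbered samples were handled together. A replicate block gave 8095 changed probe sets, 4201 higher and 3894 lower, and changed the call of no named gene, list or region. The planned tests of transposable element and ribosomal protein genes gave no value in any setting. Weakly expressed genes near the background limit what can be called.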

Other observations

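All tests in this part were chosen after the data were seen. Families of genes that share a symbol were examined with limma's camera, 37 of them with at least 6 measured genes. Of 29 measured serine carboxypeptidase-like genes 11 fell and 2 rose, with a median change of -0.11 (adjusted p = 0.032; adjusted p = 0.79 with an estimated correlation, which does not pass). SCPL49 fell from 9.68 ± 0.04 to 8.04 ± 0.06, scpl35 from 9.74 ± 0.08 to 8.31 ± 0.03 and scpl20 from 6.84 ± 0.23 to 4.95 ± 0.09 (SD, n = 3). Of 15 IQD genes, whose products bind calmodulin and act at microtubules, 8 fell and 1 rose, with a median of -0.29 (adjusted p = 0.032; adjusted p = 0.79 with an estimated correlation, which does not pass). iqd21 fell by 0.97 (SE 0.09) and iqd33 by 0.96 (SE 0.10), and IQD23 rose by 0.59 (SE 0.10). The counts of both families kept their direction under repeated quantile normalization and under centring. The symbol PDF covers 7 measured genes, of which 5 rose and 1 fell (adjusted p = 0.014; adjusted p = 0.79 with an estimated correlation, which does not pass), but it stands for unlike genes. The plant defensins PDF1.4, PDF1.2 and PDF1.2b rose by 2.35, 1.99 and 1.70, while PDF2.1 fell by 0.36. PDF1A and PDF1B, the peptide deformylases that trim proteins made in organelles, rose by 0.92 and 1.52. PDF1.2 and PDF1.2b are near-identical copies, and their probe sets may not tell them apart, so their values are not independent; PDF1.2 lies in the interval of chromosome 5 with a median change of 0.84. With an estimated correlation camera passed 0 of the 37 families (1 had an unadjusted p under 0.05).

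Transcripts of the mitochondrial genome moved both ways. Of 22 probe sets for 15 mitochondrial genes, 4 rose, 8 fell and 10 did not pass, with a median of -0.12 and a range from -1.23 to 2.23. These probe sets were dim, with a median level of 4.91. Annotated pseudogenes, measured as 989 genes with a median level of 3.18, included 28 that rose and 77 that fell (camera p = 0.18; p = 0.69 with an estimated correlation). On chromosome 2 the 566 expressed genes from AT2G21630 to AT2G47250 had a median change of 0.00 against -0.14 for the rest of that chromosome. The run statistic there was 3.17, and 0 of 100 shuffles gave a run as strong, though the strongest shuffled run was also 3.17 to the digits given.

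The interval of chromosome 5 is the pattern that most invites a closer look. The level or length of its genes is argued against, since 10000 lists matched on both gave a highest median of 0.07. Sequence differences from the probes lower the signal, which is opposite to the rise seen. With borders set from every second expressed gene, the genes held out between them had a median of 0.84, against -0.04 for those held out elsewhere. Of the genes held out between the borders 1.03% lay below -0.5 (2 of 195, exact 95% interval 0.124% to 3.66%), against 14.6% elsewhere. This low share follows from the upward shift, so it cannot show whether the segment also carries sequence differences. A hypothesis that stays open is additional copies of this segment in the double mutant, under which its genes should shift together: their interquartile range was 0.56 (95% bootstrap interval 0.48 to 0.63), within the 0.45 to 0.58 of lists of that size elsewhere. Higher transcription across an active domain with no more DNA would also give the median of 0.84, and cannot be told apart from it without a measurement of DNA.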
